A study of Homo sapiens with 6 samples.

How the data were processed

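The series holds 6 Repli-seq libraries of HT-1080, an established human fibrosarcoma cell line. Per the labels, the libraries were made from the cell-cycle fractions G1b, S1, S2, S3, S4 and G2, with 1 library each and no replicates. Repli-seq sequences DNA that was newly made in each fraction, so the fraction with the most signal gives the time at which a region replicates. Per the labels' protocols, culture followed the supplier's general conditions, and the cells were a clone in which HPRT had been knocked out by targeting, chosen to keep tetraploid cells out. The libraries were made with a TruSeq kit, and the labels' extraction protocol points to the Repli-seq track of ENCODE.

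The authors deposited 1 file of percent values per library. Each whole-percent value is the share of that fraction in the signal of a window summed over the 6 fractions, a reading taken from the values themselves, since the 6 files add up to about 100 in every window with signal. Windows step by 1 kb. The width of the windows was measured here as 50 kb, because the first window without signal lay a median of 25.1 kb inside 110 edges of assembly gaps. The authors also deposited a list of peaks and a list of valleys for the whole series, with a score at each. The deposited score was compared with values computed here and equals a smoothed weighted average of the 6 percent values. How the lists were called, the aligner, the filters on reads and the number of reads are not given in the sources used here. The genome build is hg19, per the submitters' processing notes.

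The depth of each library is unknown, because the percent files hold no counts, so no interval or detection limit was derived from reads. The exact Clopper-Pearson 95% binomial intervals given for shares of the genome count 1 window in every 50, 56857 windows in all, and those for shares of genes count genes. They cover counting error only and not the spread between cultures. Neighbouring windows have similar timing but are counted as independent, so the intervals for shares of the genome are too narrow even for counting error.

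Chromosomes 1 to 22 and X were used. Windows with 0 in all 6 files were left out, which removed 192451 windows or 6.34%. The 6 values of each remaining window were rescaled to a common sum, and the weighted average of the ENCODE track was computed. Its weights are 11, 9, 7, 5, 3 and 0 twelfths for G1b, S1, S2, S3, S4 and G2, multiplied by 100, so that a higher value means earlier replication and 91.7 is the highest possible. The scatter of a single window, from second differences of neighbouring windows that share no reads, was 1.07 points. The deposited scores were matched with a level 7 maximal-overlap wavelet smooth of this weighted average (symlet wavelet, PyWavelets). Across the 8943 landmarks the median absolute difference was 0.0318 points.

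Between a deposited peak and the next valley to its right, forks were taken to run rightward, and between a valley and the next peak to its right, leftward. A gene counted as head-on when it is transcribed against the fork direction at its midpoint, and as co-directional otherwise. Segments whose ends differ by at least 10 points are called steep here, and the others flat. Protein-coding genes came from GENCODE 44 lifted to the same build, and the value of a gene is the mean over its body.

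No test across libraries was possible. Landmarks were set against 10000 circular shifts of their positions within chromosomes, head-on shares against 10000 rotations of the gene strands within chromosomes, and list medians against 10000 random lists of as many genes matched on length decile. List medians were also set against rotations of the gene order, which keep clusters of neighbouring genes together. Each comparison is given as a percentile that describes these libraries, and a percentile below 2.5 or above 97.5 is called outside the range. Correlations across the 23 chromosomes were tested with 100000 permutations, two-sided, with Benjamini-Hochberg adjustment over 4 tests.

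The 19 gene lists were fixed before the data were examined, as were the comparisons and the rule for naming genes. The lists are targeting loci, HT-1080 loci, housekeeping genes, ribosomal proteins, replication factors, homologous recombination, extracellular matrix and mesenchymal genes, epithelial, lymphoid, neuronal and liver genes, common fragile site genes, replication-dependent histones, olfactory receptors, chromosome 19 zinc fingers, keratin-associated proteins, beta-defensins, clustered protocadherins and HOX genes. The rule names every member of the targeting and HT-1080 lists, the 2 earliest and 2 latest members of every other list, the 5 earliest and 5 latest genes of at least 200 kb, the 3 peaks with the highest and the 3 with the lowest weighted average, and the 3 longest runs of windows highest in S4 or G2. Genes named outside this rule are said to be so, and some genes that the rule selects are not reported here.

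The steps were tested on simulated data. The weighted average was recovered with a mean error of 0.00388 points and an SD of 0.869 points over 138000 windows. Fork direction from landmarks was right in 100% of 130663 windows, which was fixed because the landmarks were placed at the planted maxima and minima. From the slope of the smoothed average it was right in 99.997%. The calling of peaks and valleys was not tested. With 60% of 17962 genes made head-on against these same directions, 60.4% were found, which checks the counting and not the directions. With none planted the share was 50.0% at percentile 53.9. Of 200 unshifted lists of 25 genes, 4% fell outside the range, and of 200 lists shifted by 1 SD, 79.5% were found.

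The alternatives tried were equally spaced weights, libraries scaled to one mean, leaving out the G1b or the G2 library, every 25th window, autosomes only, a filter on the sum of the 6 values, stricter landmarks, landmarks and fork directions computed from the smoothed curve, the value at the transcription start in place of the gene body, genes held within 1 segment and at least 50 kb from a landmark, and rotations in place of random lists. The planned thinning to every 25th window assumed 25 kb windows, and every 50th was added once they were measured. Other alternatives chosen after seeing the data were leaving out windows in which 2 or more of the 6 values are 0, leaving out segments that cross 100 kb without signal, and splitting head-on shares by gene length. The work used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, PyWavelets 1.8.0 and Matplotlib 3.10.9. Coordinates of adeno-associated virus target sites were not used here.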

Results

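The data are genome-wide replication profiles of HT-1080 in 6 cell-cycle fractions, 1 library per fraction, with lists of peaks and valleys of the combined profile. There are no replicates, so differences between libraries have no replicate check, and the depth of each library is unknown. The study asked how replication forks and the direction of transcription relate to gene targeting by adeno-associated virus vectors, which are used to edit a chosen locus by recombination. Averaged over windows with signal, the libraries held 16.2% of the signal in G1b, 16.9% in S1, 17.0% in S2, 16.8% in S3, 16.6% in S4 and 16.5% in G2.

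The first comparison asked when each part of the genome replicated. G1b was the highest fraction over 518 Mb, which is 18.2% of the genome with signal (95% CI 17.9 to 18.5), and G2 was the highest over 314 Mb, or 11.05% (10.8 to 11.3). The shares of S1, S2, S3 and S4 were 18.5%, 16.6%, 17.6% and 18.1%. These shares depend on how the libraries were scaled against each other, and the libraries hold near equal parts of the signal. They therefore do not measure how much DNA replicated in each fraction. Chromosome 22 had the largest part highest in G1b, 47.2%, and chromosome 4 the smallest, 4.15%. The X chromosome had the largest part highest in G2, 26.8%, and chromosome 17 the smallest, 1.68%. Windows highest in G1b held a mean of 50.6% of their signal in G1b, 23.1% in S1 and 10.99% in G2, and windows highest in G2 held 49.95% in G2 and 29.9% in S4. Across windows, S1 and S4 had a Pearson correlation of -0.850, and the adjacent fractions S4 and G2 one of 0.595. These correlations are across windows of single libraries, and windows are not independent replicates.

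**Figure D1:**
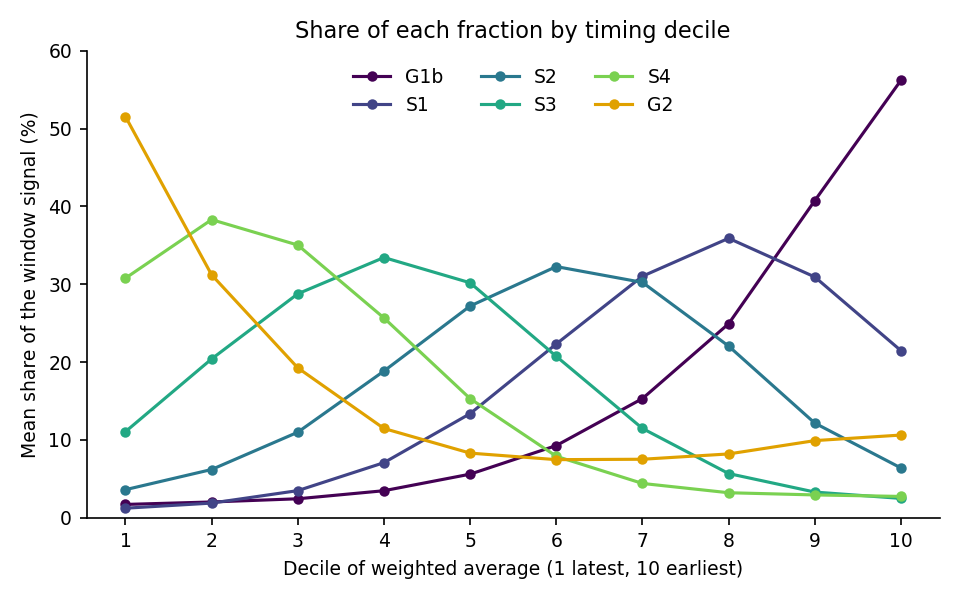
Mean share of the window signal (%) in each fraction, by decile of the weighted average from the latest windows (1) to the earliest (10). The G2 line falls from 51.5% in the latest decile to 7.47% in decile 6 and stands at 10.6% in the earliest decile.

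The chromosomes differed widely in timing. Chromosomes 22, 17 and 19 were the earliest, with median weighted averages of 68.6, 67.7 and 66.2, against a genome median of 51.2 (interquartile range 32 to 65.9). The X chromosome and chromosomes 4, 21 and 13 were the latest, with medians of 39.0, 39.1, 40.3 and 43.3. Chromosome 19, with 26.4 protein-coding genes per Mb, also held a late part, and 19.4% of its windows were highest in S4 or G2. The X chromosome was 12.2 points below the genome median, a gap of -12.2 that became -8.03 without the G1b library. The leads of chromosomes 22, 17 and 19 over the genome were 17.4, 16.5 and 15 points, and 6.002, 5.72 and 3.09 points without the G1b library. Chromosomes 15, 20 and 1 were then ahead of chromosome 19, at 4.82, 3.95 and 3.69 points. Windows highest in G1b held 8.72% in S2 and 10.99% in G2, against 23.1% and 7.80% in windows highest in S1. With G1b left out, the former score later than the latter. This comes from G2, the fraction with the lowest weight, which holds a larger part of the signal left in the former. The origin of that G2 share stays open below. Values without the G1b library, here and below, therefore do not rank the earliest DNA.

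Chromosomes rich in genes and in GC were earlier. Over the 23 chromosomes, the median weighted average correlated with genes per Mb (r = 0.752, rho = 0.854) and with GC content (r = 0.873, rho = 0.897). Each permutation p was 1e-05, the smallest that the permutations can give, and 1e-05 after adjustment over 4 tests. Without the 2 chromosomes farthest from the median gene density, 19 and 17, r was 0.827, and without the 2 farthest in GC content, 19 and 22, r was 0.839. From the latest to the earliest decile of windows, mean GC content rose from 37.2% to 47.1% and the density of transcription starts from 1.13 to 20.7 per Mb.

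**Figure D2:**
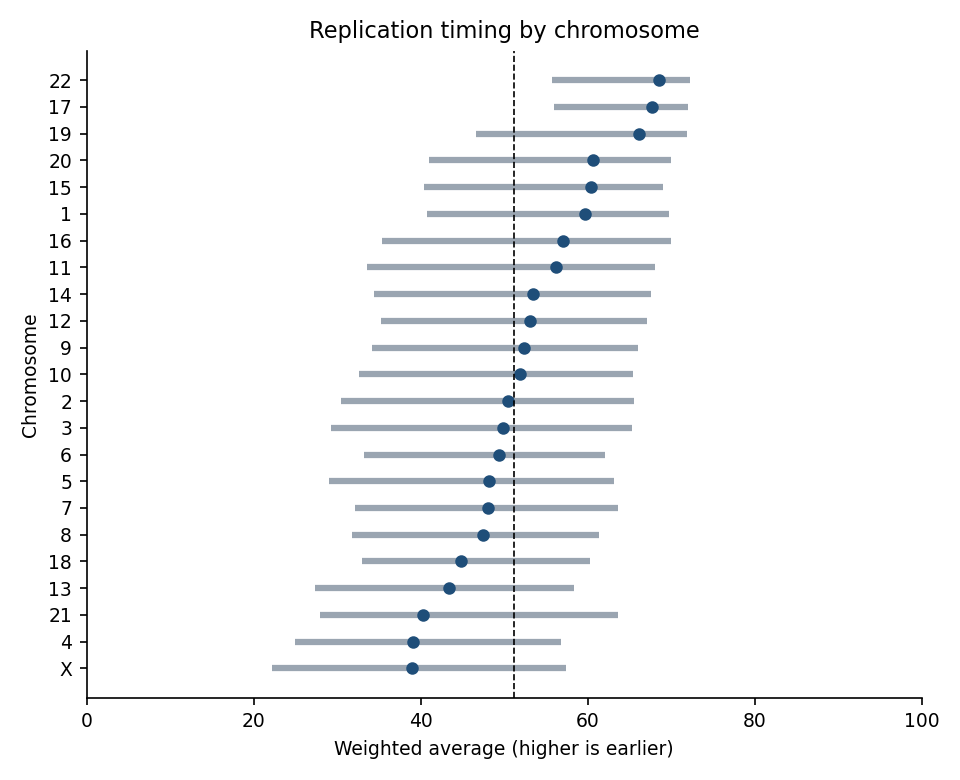
Median weighted average (points) of each chromosome, with bars for the interquartile range over windows and a dashed line at the genome median of 51.2. Chromosome 22 is at 68.6 and the X chromosome at 39.0.

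The longest late regions lie on chromosomes 13 and 4. The longest run of windows highest in S4 or G2 spans chromosome 13 from 61374501 to 71938500 (10.6 Mb) and holds the protocadherin genes PCDH20 and PCDH9 and the gene KLHL1, with a mean weighted average of 24.5. A run of 10.1 Mb on chromosome 4 from 27110501 to 37194500 holds PCDH7, ARAP2 and DTHD1, with a mean of 24.6. Another on chromosome 4, from 58488501 to 68076500 (9.59 Mb), holds ADGRL3, TECRL and EPHA5. It had a mean of 20.3, and 63.3% of its windows were highest in G2.

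The peaks and valleys are the series' candidate sites of replication initiation and termination. Among the 4479 peaks and 4464 valleys, the lowest peaks lie in late DNA. The peak at chromosome 3, 2411501 to 2412500, inside CNTN4, which encodes a contactin, had a weighted average of 9.18 and 74% of its signal in G2. The peaks at chromosome 5, 116836501 and 165525501, had 9.33 and 9.42 and lie 926 kb from SEMA6A and 880 kb from TENM2, the nearest genes. The 3 peaks with the highest values were on chromosome 7 at 74801501 near GATSL2 (91.67), chromosome 1 at 147906501 near PPIAL4A (88.8) and chromosome X at 48247501 in SSX4 (84.5), each in a window where at least 3 of the 6 values were 0. Among peaks in windows without such a 0, a choice made after the values were seen, the highest were near CTAG2 on the X chromosome at 153871501 (79.2), in LRRC37A3 on chromosome 17 at 62852501 (78.5) and in CCT3 on chromosome 1 at 156305501 (78.4).

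Peaks and valleys alternated without exception, with median spacings of 504 kb between peaks (interquartile range 316 to 866) and 532 kb between valleys (333 to 864). The 4308 peaks in windows with signal had a mean weighted average of 55.2 (SD over peaks 19.5) and the 4194 valleys one of 45.9 (SD over valleys 20.7), a difference of 9.32. Shifted peak positions gave means from 48.4 to 49.2. Peaks are local maxima and valleys local minima of a smooth of the same average, so their order is fixed by construction and only the size of the difference is informative. Of the peaks, 38.6% were highest in G1b and 9.10% in G2. Many neighbouring landmarks differ little: of 8379 segments with signal at both ends, 27.4% had ends less than 2.14 points apart, which is 2 times the scatter of a window. Requiring larger differences left 500 peaks and 618 valleys. The 2486 steep segments had a median length of 608 kb and a median slope of 3.62 points per 100 kb, and covered 57.5% of the genome with signal.

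Peaks lay near the starts of genes. A protein-coding transcription start was within 50 kb of 52.5% of peaks, against 38.7% on average for shifted positions (central 95% of shifts 37.4 to 39.9), and of 35.9% of valleys. These shifted positions were not matched on timing. Peaks are earlier than shifted positions by construction and starts are denser in early DNA, so part of the gap can come from timing. Splits by fraction compare landmarks with shifted positions highest in the same fractions. Among peaks highest in S2 or S3 the share was 44.4% against 32.6%, and among peaks highest in G1b or S1 71.7% against 63.7%. Valleys highest in G1b or S1 also lay near starts more often than shifted positions, 67.3% against 64.6%. Inside the bodies of genes lay 44.5% of all peaks and 48.2% of all valleys, each against 46.5% for shifted positions. The gap was widest among landmarks highest in S2 or S3, with 33.7% of peaks against 45.0% and 52.2% of valleys against 45.2%. All of these shares lay outside the range of the shifts. The share of S4 or G2 peaks near a start, 13.4% against 11.9%, and that of S4 or G2 valleys inside genes, 27.0% against 27.2%, lay inside it.

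The HPRT1 gene, which encodes the purine salvage enzyme that the clone lacks, lies on chromosome X from 133594195 to 133654543 on the plus strand. It replicated early, with a weighted average of 72.6, 51.8% of its signal in G1b and 25.9% in S1. A peak lies inside the gene at 133604501 to 133605500 (72.4), a valley follows at 133740501 (71.4) and a higher peak at 133907501 (77.6), while the valley on the left at 132619501 is late (19.4). By these landmarks forks ran leftward at the transcription start and rightward at the midpoint and the end, where the gene counted as co-directional. In single windows the peak and the next valley differ by less than the scatter of 1 window, 1.071 points, and in the deposited smoothed score they stand at 72.5 and 69.7, so the direction over the gene rests on a small difference. Beside the peak, at 133603501, G1b held 51%, S1 27% and G2 11%. Beside the valley, at 133733501, they held 60%, 12% and 15%. The G1b share alone thus orders these windows the other way, and the co-directional call is uncertain. The percent values are shares within 1 clone and cannot show the knockout itself.

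**Figure D3:**
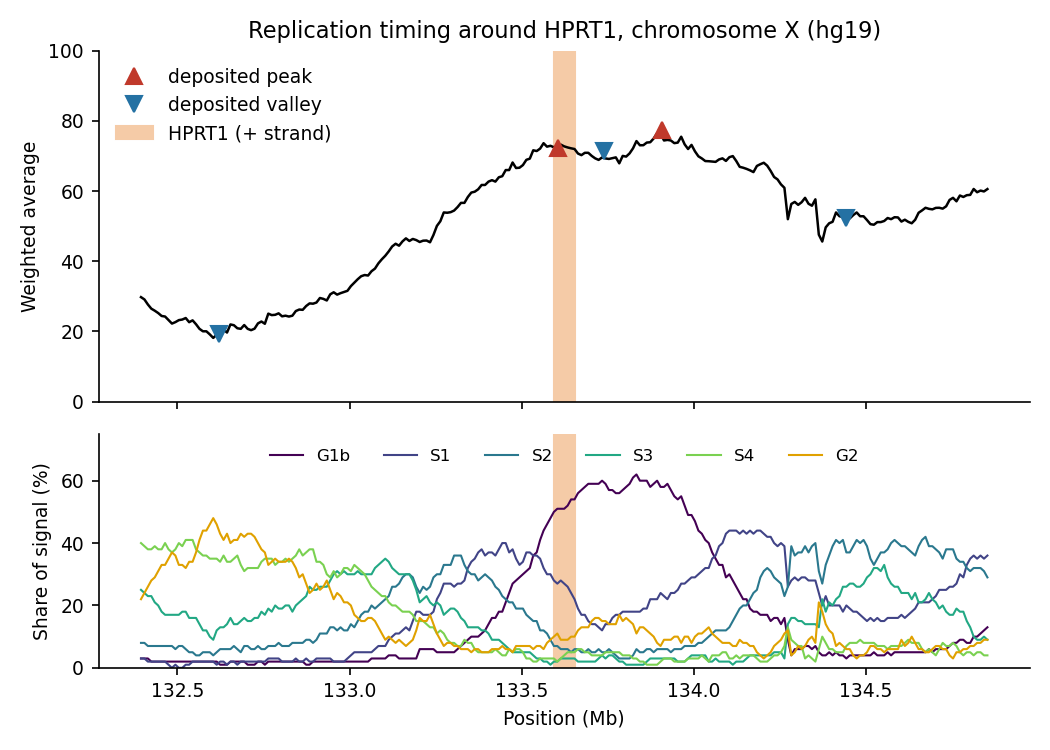
Weighted average (points, top) and share of the window signal in each fraction (%, bottom) along chromosome X around HPRT1 (shaded), with the peaks and valleys as triangles. The curve climbs from 19.4 at the left valley to 72.4 at the peak inside the gene.

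The next comparison asked when loci used for gene targeting replicated and how they are oriented. By weighted average, COL1A1, a collagen gene, was the earliest of the 11 targeting loci at 74.7. It was followed by HPRT1, PPP1R12C at 71.6 and the lamin gene LMNA at 70.4. B2M was at 64.7, IL2RG at 64.5, COL1A2 at 62.3 and PIGA at 61.5. CLYBL (56.6) and the albumin gene ALB (53.9) were the latest, both highest in S2. The G1b share alone gives another order, with 72.6% in COL1A1, 70.1% in LMNA, 51.8% in HPRT1 and 45.6% in PPP1R12C. LMNA had the largest G2 share of the 11 loci. A G2 share lowers the weighted average, and its origin in early windows stays open below. Of the 11 loci, 3 were head-on, LMNA and ALB among them, and 8 co-directional, with HPRT1 counted among the 8 although its direction is uncertain. The median of the list, 64.7, was at percentile 18.9 among random lists, inside the range, and at percentile 84.2 without the G1b library.

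Of the loci often discussed in this line, the MYC oncogene was early at 71.2, and TERT, IDH1 and NRAS were in mid S phase at 59.97, 57.3 and 56.7. MTAP (45.8), CDKN2A (28.3) and CDKN2B (25), neighbours on chromosome 9, had low values, but 66.2% of the windows of MTAP and 100% of those of the other 2 had 2 or more values at 0. The list median of 57.0 was at percentile 2.82. Without these 3 genes it was 59.97, at percentile 9.57. MYC, TERT, IDH1 and NRAS were head-on.

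The fork map gave rightward forks over 49.6% and leftward forks over 49.7% of the genome with signal, with 0.715% undefined, and between 48.5% and 52.1% rightward on single chromosomes. Of 19827 protein-coding genes, 9880 or 49.8% were head-on (95% CI 49.1 to 50.5), inside the range of the rotations, 49.2 to 50.7 (percentile 35.1). In steep segments the share was 49.9%, at percentile 45.1.

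With genes split by length into 4 classes of equal size, the longest class (71.4 kb and longer) stood apart. In steep segments, its genes were head-on in 1231 of 2709 cases, or 45.4% (95% CI 43.6 to 47.3), below all 10000 rotations. The second class (9.50 to 27.3 kb) was head-on in 53.6% of cases (51.5 to 55.8), at percentile 99.955. Over all segments the longest class was at 48.0% (46.6 to 49.4), at percentile 0.365, and the second at 51.4%, inside the range. Genes with midpoints 50 to 100 kb from a peak were at 48.2%, percentile 1.05. These are 5 of 29 groups of genes examined, without correction for their number, and the length classes were chosen after seeing the data.

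**Figure D4:**
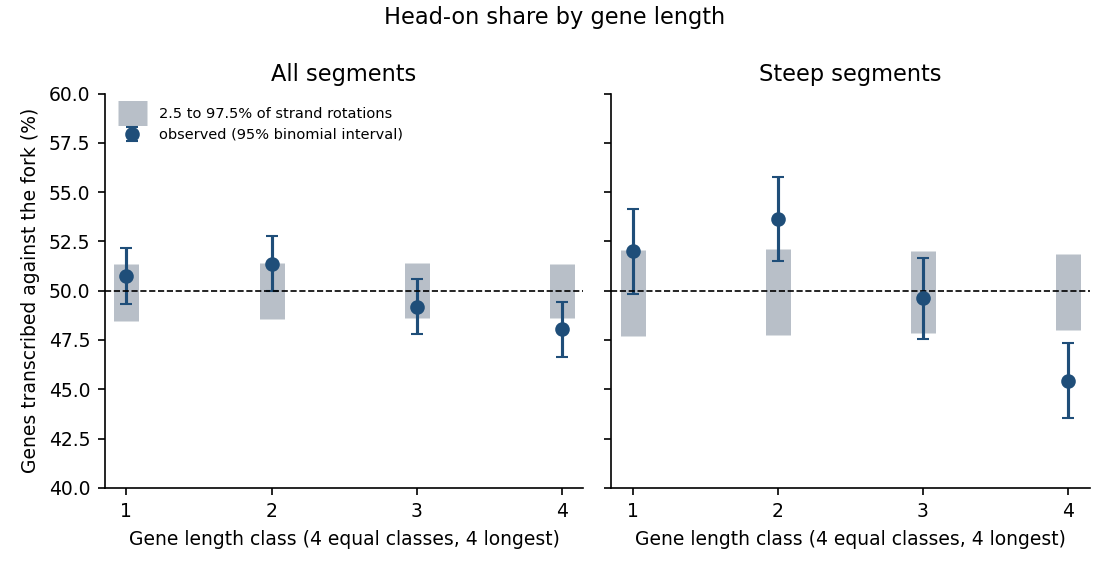
Share of genes transcribed against the fork (%) by gene length class, over all segments (left) and in steep segments (right). Points carry 95% binomial intervals and grey bars span the central 95% of strand rotations; in steep segments the longest class is at 45.4% and the second at 53.6%.

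Genes as a whole were early. The median of 20071 protein-coding genes was 67.4 (interquartile range 56.4 to 71.9), 44.6% were highest in G1b, 23.7% in S1 and 6.87% in S4 or G2. The 1498 genes of at least 200 kb had a median of 53.6. The earliest of these were MARK4 (74.6), OSBPL9 (74.2), NR6A1 (73.7), MRPL33 (73.7) and CSTPP1 (73.6). The latest were KHDRBS2 (10.5), CNTN4 (11.5), MCTP2 (12.4), RTL4 (13.1) and MYT1L (13.1), a neural transcription factor gene. In the longest decile of genes 17.6% were highest in S4 or G2, against 5.33% in decile 2 and 12.4% in the shortest decile.

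Genes of common fragile sites, which break under replication stress, were the latest list with a median of 28.7. CSMD1 (13.6) and CNTNAP2 (14.9) were the latest and RORA (54.5) and DPYD (53.8) the earliest. All 20 were below the median of all genes, 16 were highest in S4 or G2, and the list was below all 10000 random lists matched on length decile. The longest decile runs from 161 to 2474 kb, and length within it was not matched. Neuronal genes had a median of 41.9, at percentile 0.02. The receptor gene GABRB2 (14.4) was late, while SLC17A7 (73.8) and SYN1 (69.8) were early.

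Several gene clusters replicated in middle or late S phase. The 67 replication-dependent histone genes, which supply histones during DNA synthesis, had a median of 46.3, and 36 of them were highest in S3. H4C12 (35.5) and H2AC15 (35.7) on chromosome 6 were the latest, and H2BC12L (70.5) and H2BC21 (69.6), on other chromosomes, the earliest. The 398 olfactory receptor genes had a median of 46.6 and ranged from OR5F1 (10.7) and OR4C11 (10.8) to OR6J1 (72.9) and OR13J1 (73.3). Zinc finger genes of chromosome 19 had a median of 52.8, with ZNF676 (9.72) and ZNF492 (9.97) late and ZNF526 (74.1) and ZNF296 (74.0) early. These 3 lists were below all random lists, and at percentiles 1.37, 0.0125 and 0.0374 among rotations. Without the G1b library the histone list was at percentile 3.68, inside the range.

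For other clusters the position depended on the comparison. All 53 clustered protocadherin genes were below the median of all genes, from PCDHB13 (45.6) and PCDHB12 (45.8) to PCDHA2 (59.7) and PCDHA1 (59.9). Their median of 56.2 was at percentile 0.1 among random lists, 15.1 among rotations and 35.4 without the G1b library. Beta-defensins, from DEFB131A (24.2) and DEFB114 (33.8) to DEFB132 (72.4) and DEFB129 (73.0), had a median of 61.8, at percentile 0.96 among random lists, 18.1 among rotations and 93.1 without the G1b library. Keratin-associated protein genes were split: 33 of 94 were highest in G2, with KRTAP19-5 (18.4) and KRTAP13-4 (19.5) on chromosome 21 the latest, and KRTAP2-4 (71.04) and KRTAP2-3 (70.5) on chromosome 17 the earliest. Their median of 65.2 was at percentile 49.8, and at 99.6 without the G1b library. HOX genes, which pattern the body axis, ran from HOXD13 (43.3) and HOXD12 (44.1) to HOXB1 (73.1) and HOXB5 (73.3), with a median of 67.7 at percentile 33.4, and at percentile 100 without the G1b library.

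Housekeeping genes had the highest median, 71.1, with 17 of 21 highest in G1b. ALDOA (74.9) and GAPDH (73.9) were the earliest, and TBP (50.3) and SDHA (61.4) the latest. Ribosomal protein genes had a median of 70.9. RPL19 (75.2) and RPL35 (75.1) were the earliest, and RPL10L (35.5), an autosomal retrocopy, and RPL38 (41.3) the latest. The lists were at percentiles 89.3 and 96.5, inside the range, and at 99.5 and 99.2 without the G2 library and 9.84 and 23.6 without the G1b library. Ribosomal protein genes were at percentile 99.91 among rotations.

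**Figure D5:**
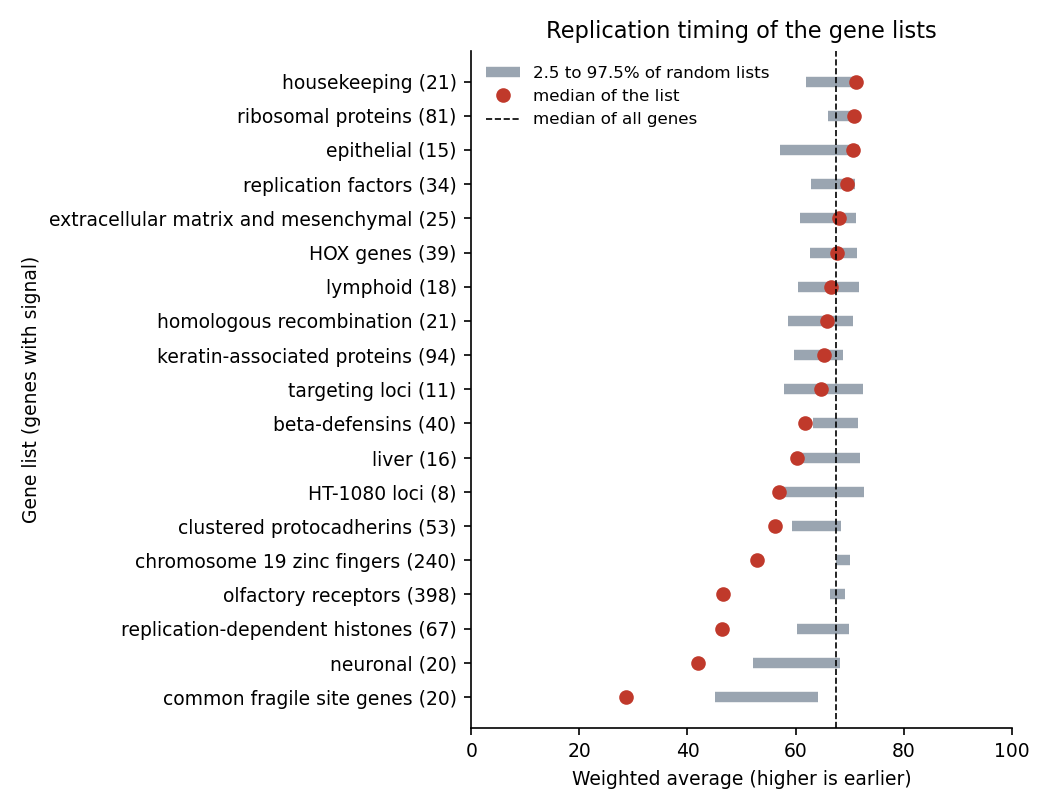
Median weighted average (points) of the 19 gene lists, with bars for the central 95% of random lists matched on gene length decile and a dashed line at the median of all genes, 67.4. Common fragile site genes are the latest at 28.7 and housekeeping genes the earliest at 71.1.

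The remaining lists were inside the range. Replication factors had a median of 69.5 (percentile 77.7, and 24.4 without the G1b library), with MCM5 (74.4) and CLSPN (74.3) early and the origin recognition genes ORC4 (29.7) and ORC5 (40.3) late. Homologous recombination genes had a median of 65.8 (percentile 44.2, and 62.4 without the G2 library), from PALB2 (50.3) and XRCC2 (51.3) to XRCC3 (75.8). Extracellular matrix and mesenchymal genes had a median of 68.1 (percentile 56.6, 5.51 without the G1b library and 49.955 without the G2 library), with COL3A1 (43.2) and COL5A2 (46.4) late and COL1A1 and PDGFRB (74.6) early. Epithelial genes had a median of 70.6 (percentile 89.6), from TP63 (45.2) and GRHL2 (57.8) to MUC1 (73.3) and EPCAM (73.8). Lymphoid genes had a median of 66.5 (percentile 31.9), with IKZF1 (33.2) and MS4A1 (43.7) late and CD4 (74.8) early. Liver genes had a median of 60.3, at percentile 2.78, at 2.2 without the G2 library, 42.4 without the G1b library and 10.1 among rotations, from the fibrinogen genes FGB (39.4) and FGG (40.6) to APOC3 (71.7) and APOA2 (73.6).

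The last comparison asked how far replication of a window was spread over fractions. The SD of the fraction rank, counted from 1 for G1b to 6 for G2, had a median of 1.27 (interquartile range 1.14 to 1.43). Of all windows, 41.1% had 2 separated maxima among the 6 values (95% CI 40.6 to 41.4), with a low point at most 0.5 of the lower maximum. The share depends on that limit and was 15.2% at 0.25 and 49.4% at 0.75. Among windows highest in G1b the share was 95.6%, among those highest in S1 73.7%, in G2 43.0% and in S3 0.521%. The second maximum was low in nearly all: both maxima reached 20% in 0.212% of windows. In windows highest in G1b, mean shares were 3.18% in S4 and 10.99% in G2, the G2 share whose origin stays open below. In windows highest in G2, they were 1.97% in G1b and 1.64% in S1, so small steps of whole-percent values can decide the call. The share with 2 maxima is therefore not a direct measure of spread.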

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

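The alternatives that leave out windows with 2 or more values at 0, leave out segments that cross 100 kb without signal, take every 50th window or split genes by length were chosen after seeing the data. For results that answer a comparison, 153 alternatives left the value or its direction and side of the range as they were, 6 moved a value outside the range, 4 moved one inside it, 12 changed a direction (2 of them also moving outside the range and 1 inside it) and 19 moved a value beyond its error. For the other results, which are single chromosomes, named genes and the remaining length classes, the counts were 158 unchanged, 144 moved and 5 changed in direction. These counts leave out peaks against valleys and the filter on the sum of the 6 values, whose outcomes are fixed by construction. They keep the alternative without genes in windows with 2 or more values at 0, which removed members from the HT-1080 list only. Changes without the G1b library follow at least in part from the lost ranking of the earliest windows described above. The cause was not tested for any other change below.

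Peaks lie above valleys by construction, and the size of the difference was 6.59 points without the G1b library and 22.6 with stricter landmarks, which select for it. Head-on shares of all genes were between 49.6% and 49.9%. In the longest of the 4 length classes they were between 43.7% and 48.0%, and in its steep segments between 43.3% and 45.4%, outside the range under every alternative tried. The lists of fragile site, neuronal, olfactory receptor and chromosome 19 zinc finger genes stayed below the range under all 6 alternatives.

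Libraries scaled to one mean gave shares of 18.7% for G1b, 17.97% for S1, 15.9% for S2 and 11.7% for G2, and autosomes alone 18.8% for G1b and 10.2% for G2. Equally spaced weights put the median of all genes at 71.7, the lead of chromosome 22 at 21 points and the gap of the X chromosome at -14.2. Without the G1b library these values were 6.002 and -8.03, chromosome 6 moved from below the genome median to 0.487 above it, and without the G2 library 19.4 and -10.9. Stricter landmarks left 500 peaks spaced by 3670 kb and 618 valleys spaced by 3064 kb, by construction. A low point of at most 0.25 of the lower maximum gave 15.2% of windows with 2 maxima, and one of 0.75 gave 49.4%.

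Measured at the transcription start, the head-on share was 52.1% in the second length class, and 51.7% in the third, a change of direction from 49.2%, both now outside the range. In steep segments alone the second class was at 53.6%. MTAP and DPYD were 5.92 and 0.387 points above the median of all genes at their starts and below it over their bodies, and SYN1 was at -0.184 at its start and above the median over its body. Keratin-associated protein genes were at percentile 52.0 at the start.

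Without the G1b library the percentiles were 84.2 for targeting loci, 9.84 for housekeeping genes, 23.6 for ribosomal proteins, 24.4 for replication factors, 5.51 for extracellular matrix genes, 3.68 for histones, 99.6 for keratin-associated proteins, 93.1 for beta-defensins, 35.4 for protocadherins and 100 for HOX genes. Without the G2 library they were 99.5 for housekeeping genes, 99.2 for ribosomal proteins, 62.4 for homologous recombination, 49.955 for extracellular matrix genes and 2.2 for liver genes. Among rotations they were 99.91 for ribosomal proteins, 18.1 for beta-defensins, 15.1 for protocadherins and 53.1 for HOX genes.

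The filter on the sum of the 6 values removed 0 windows, so it tested nothing. No paired analysis was possible because each fraction holds 1 library. The percent files give no depth, so how far sequencing depth limits these values is unknown.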

Other observations

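All 3 patterns weighed here were noticed in the data, and the tests of the fixed sum of the values, of GC content, of early DNA in the G2 library, of assembly gaps and of DNA loss were chosen after the result was seen. The design gives no groups of cultures to compare, so no biological explanation was tested between groups, and the tests weigh properties of the libraries, of the line's genome against the reference, and of gene positions.

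Windows with 2 or more values at 0 made up 0.495% of windows with signal, and 43.3% of them lay within 50 kb of an assembly gap. They formed 91 runs of 50 kb or longer, 46 of them away from gaps. The longest, 276 kb on chromosome 5 from 69255501 to 69531500, holds SMN2, and a run of 230 kb nearby holds its copy SMN1; both genes are named after their values were seen. Local scatter on the X chromosome was 1.40 times that of the autosomes at equal timing (1.29 to 1.61 over timing deciles), and 1.27 times on chromosome 22 (0.876 to 2.36). Genes of 100 to 200 kb had starts 0.279 points earlier than their ends, at percentile 99.8 among strand rotations, while genes of 500 kb and longer had starts later by a difference of -1.39, inside the range. The differences for genes under 50 kb, of 50 to 100 kb and of 200 to 500 kb were -0.0263, 0.0360 and 0.415, also inside it. There was no correction for the number of length classes.

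The run around CDKN2A on chromosome 9, from 21848501 to 22030500 (182 kb), covers CDKN2A, CDKN2B and part of MTAP. Its flanks were early, with 58.9% and 58.8% of the signal in G1b, and the run had a weighted average of 32.04 with 51.8% of its signal in S4. Reads shared with copies elsewhere would leave few unique sequences, but 85.7% of its sampled 32-base sequences occur once in the reference, against 85.5% of the genome and at most 5.56% in the other 45 runs away from gaps. An assembly gap is also argued against, since 0% of its windows lie within 50 kb of one. Loss of this DNA in the cells is a candidate explanation that stays open: 65.1% of its values were 0, but the percent files hold no tags per window, so the share of cells or copies without this DNA cannot be given and the timing of these genes here is uncertain.

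The share of G2 rose again in the earliest windows, from 7.47% in decile 6 to 10.6% in the earliest decile, by 3.2 points and on 23 of 23 chromosomes (1.53 to 4.08). GC content is argued against only within windows highest in G1b, where 104.8% of the slope of the G2 share on the G1b share was kept with GC content in the fit. That fit does not compare them with the mid-S windows of decile 6. Mean GC content was 41.1% in decile 6 and 47.1% in the earliest decile, so GC content stays open for the rise between them. A fit within the earliest 2 deciles decides nothing because the ranking itself ties G1b to G2. A fixed sum of the 6 values acting on level late signals is argued against within windows highest in G1b, since it raises the late shares together. In these windows S4 had a slope of -0.0380, above 0 on 0 of 23 chromosomes, and S3 one of -0.112. Early-replicating DNA in the G2 library stays open: in windows highest in G1b the slope of G2 was 0.113 and above 0 on 23 of 23 chromosomes, which restates the pattern and decides nothing. Tetraploid G1 cells or cell doublets in the G2 gate, DNA labelled after S phase, and a lower total signal together with a falling S4 signal, for which totals are not in the percent files, were not tested and stay open, and the labels name a clone chosen to keep tetraploid cells out.

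In steep segments, long genes were head-on less often than strand rotations gave, 45.4% in 2709 genes, and 17 chromosomes had more co-directional than head-on long genes while 5 had fewer. The 3 chromosomes with the largest excess do not carry the pattern, since 46.7% remained without them, below the rotations (47.8 to 52.1). Transcription starts close to peaks stay open as an explanation. Long genes in steep segments were head-on in 13.9% of 396 cases with the start within 50 kb of a peak. With the start 50 to 200 kb away the share was 40.1% of 857, and over 200 kb away 57.1% of 1456. The nearer groups lay below the rotations (44.9 to 54.8 and 46.7 to 53.3) and the farthest above them (47.3 to 52.5). The distance of a start from a peak partly fixes the fork direction over the gene, so the test decides nothing.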
